A study of Mus musculus with 7 samples.

How the data were processed

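RNA from 7 whole ankles of arthritic DBA1 mice was sequenced on an Illumina NextSeq, per the labels, 3 ankles with a control microRNA and 4 with the miR-17-5p mimic. The deposited values are FPKM per gene and library, per the file headers, with the joined exon length, exon positions and an Entrez number for each of 27179 genes. The submitters' processing notes name bcl2fastq 2.20, STAR 2.5.2b, featureCounts, Subread and DESeq2 1.14.1, with no role given, and the builds mm10 and GRCm38. The strand setting, the annotation release and the library kit are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Of the Entrez numbers, 25275 matched a symbol in a RefSeq gene table of the same build.

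Multiplied by gene length, the deposited FPKM values were whole multiples of a single step per library for 100% of values, within 0.01 of a read, which gave the reads behind each value. These totals, from 27465276 to 31118975, set the depth: 1 read in a gene of 1 kilobase was worth between 0.0321 and 0.0364 FPKM. Over the 21 pairs of libraries a chi-square of the reads gave at least 17.6 per gene, so no pair differed by as little as sampling noise. This argues against a single library given under different names, but cannot tell separate ankles or animals from repeated preparations. Each library was counted as a replicate.

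The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 0.5), over the 13418 genes with a mean of at least 1 FPKM in the 7 libraries, with group as the single factor. Fold changes are the mimic group minus the control group on that log scale, which understates the change of low genes. Adjusted p-values follow Benjamini and Hochberg, 2-sided, at 0.05. A total of 26 gene lists with 483 entries, of which 2 had no match, was tested with camera at a preset inter-gene correlation of 0.01, then with the estimated correlation and with fry, for lists with at least 5 genes tested. Cell type lists were also averaged per library and compared by an exact permutation test over all 35 splits of the libraries. The same test was run on the other lists.

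Matches to the miR-17-5p seed were searched in the longest annotated 3 prime UTR of each gene (GENCODE, mouse release M21). Genes with an 8mer GCACTTTA or a 7mer GCACTTT or CACTTTA were compared with genes holding none of these nor CACTTT, over 12635 tested genes with a UTR. Every heptamer made of the same bases was treated in the same way.

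The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the genes with the smallest p, up to 5 in each direction, since none passed, passing over predicted genes and pseudogenes. It added a fixed set of genes, among them Stat3, Jak1, Il6, Il1b, Tnf, Acp5, Ctsk, Mmp3, Mmp13, Tnfsf11, Mir17hg, Cdkn1a and Tgfbr2, and from each list the 3 members with the smallest p where camera passed and otherwise 1. Alternatives were other pseudocounts (0.1 and 1), other filters on low values (none, or a mean of at least 5 FPKM), median-of-ratios scaling, quantile normalization, no variance trend, library weights, the replicate number as a block, the muscle or erythroid list mean as a covariate, and leaving out each library. Chosen after the data were seen were limma-voom on recovered reads, covariates from the neutrophil, immediate early and macrophage lists, an index of clock genes, and genes with at least 2 seed matches. The replicate block takes its group difference from the replicate numbers found in both groups, 2 and 5, alone.

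The tests were run on simulated data built from the libraries' own means and spreads, with 13410 genes in the mimic against control comparison. Each gene was drawn independently, without the differences that many genes share between the real libraries, whose first principal component held 52.7% of the variance. The rates below may therefore not hold for the real libraries. The limma test called 38.8% of genes simulated with a 1.5-fold change, 83.7% of those with a 2-fold change, 95.7% with a 4-fold change and 95.9% with an 8-fold change, and 11 of 13216 unchanged genes. In a separate simulation with 13404 genes, likewise drawn independently, an equal shift of -0.1 in every seed gene was recovered as -0.090, with rank 1. Versions of other tools were Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.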

Results

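Messenger RNA was profiled by sequencing in whole ankles, with the skin removed, of DBA1 mice with collagen-induced arthritis, a model in which immunisation against collagen inflames and erodes the joints. The ankles had been injected into the joint with a lipoplex, a lipid carrier, loaded with a mimic of the microRNA miR-17-5p (n = 4) or with an irrelevant control microRNA (n = 3). The 7 libraries held between 27465276 and 31118975 assigned reads, and between 13130 and 13470 genes stood at 1 FPKM or above in each. The labels do not say whether the ankles of a group came from separate animals, so p-values measure the spread between these samples. The comparison asked how raising miR-17-5p altered gene expression in the arthritic ankle, with attention to inflammation, bone resorption and the JAK/STAT pathway.

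The ankles given the miR-17-5p mimic held more transcript of interferon-stimulated genes and less of inflammatory mediators, cell division genes and osteoclast genes than those given the control microRNA. Ifit3, an interferon-induced antiviral gene, stood at 25.9 ± 3.18 FPKM (SD, n = 3) in control ankles and 70.8 ± 19.4 FPKM (SD, n = 4) in mimic ankles. Il6, the central cytokine of the IL-6 family, stood at 40.5 ± 9.20 FPKM in control ankles and 13.6 ± 11.7 FPKM in mimic ankles. Acp5, which encodes the tartrate-resistant acid phosphatase of osteoclasts, stood at 805 ± 32.3 FPKM and 666 ± 42.8 FPKM. No single gene passed the test over all genes, and the gene groups passed camera only with a preset correlation between genes. Camera with that preset also passed from 5 to 17 lists in splits of the libraries that mixed the groups. With an estimated correlation 0 of 26 lists passed (camera adjusted p = 0.486 for each of the 4 groups above). The estimates were 0.665 for interferon-stimulated genes, 0.414 for inflammatory mediators, 0.844 for cell division genes and 0.415 for osteoclast genes. With fry's test of a shared direction 0 passed as well, while its mixed test, which lets members move either way, passed 14. For cartilage genes the estimated correlation, 0.00102, lay below the preset value. Their camera adjusted p was still 3.24e-05 with the preset and 0.126 with the estimate, so a higher correlation cannot account for that loss.

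Of 13418 genes tested with limma, 0 were higher and 0 were lower at an adjusted p under 0.05, and the lowest adjusted p was 0.148. At an unadjusted p under 0.05 there were 2356 genes, 1003 higher and 1353 lower in the mimic ankles, where chance gives about 671. With limma-voom on recovered reads, chosen after the data were seen, 0 genes passed and 2365 had an unadjusted p under 0.05. The groups did not overlap at 2055 genes, 15.3% of those tested, where chance gives 5.71%. Without control replicate 2, 115 genes were higher and 203 lower at an adjusted p under 0.05, and 3833 had an unadjusted p under 0.05. Without control replicate 5 the unadjusted count was 1216. Leaving out any library other than control replicate 2 gave 0 genes at an adjusted p under 0.05. With all 7 libraries, a split that mixed the groups gave 155.

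None of the 10 named genes with the smallest p, 5 in each direction, passed over all genes. Among those higher in mimic ankles, Agrn, which encodes the basement membrane proteoglycan agrin (mm10 chromosome 4, 156165290 to 156197488), stood at 16.7 ± 0.51 FPKM in control and 24.5 ± 1.44 FPKM in mimic ankles, a log2 fold change of 0.54 (SE 0.063, limma adjusted p = 0.148). Iigp1, an interferon-inducible GTPase (chromosome 18, 60376029 to 60392634), had a log2 fold change of 1.36 (SE 0.21), and Tnfsf10, which encodes the death ligand TRAIL (chromosome 3, 27317077 to 27339665), of 0.71 (SE 0.10). Phf11d (chromosome 14, 59347407 to 59365490) had a log2 fold change of 0.97 (SE 0.11) and Tgtp2 (chromosome 11, 49057196 to 49064212) of 1.32 (SE 0.17), the latter uncertain because Tgtp1 is nearly identical. Among those lower, Rrad, a small GTPase of the Rad family (chromosome 8, 104628066 to 104631321), stood at 22.6 ± 2.01 FPKM in control and 12.8 ± 1.15 FPKM in mimic ankles, a log2 fold change of -0.79 (SE 0.089, limma adjusted p = 0.148). Wfdc17 (chromosome 11, 83704056 to 83706269), Cd33, a sialic acid-binding receptor of myeloid cells (chromosome 7, 43527456 to 43533171), Relt, a member of the TNF receptor family (chromosome 7, 100845848 to 100863413), and Pimreg (chromosome 11, 72042502 to 72047370) had log2 fold changes of -0.71, -0.91, -0.51 and -0.63. Without control replicate 2, each of these 10 genes except Iigp1 passed with limma, at adjusted p from 0.0219 (Cd33) to 0.0425 (Tgtp2). None passed when any other library was left out.

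The list of interferon-stimulated genes was higher in the mimic ankles: all 24 members had a higher mean, with a median log2 fold change of 0.88. Of these, 21 were higher with p adjusted over the list alone and 0 over all genes tested. Ifit3 (chromosome 19, 34583529 to 34588982) had a log2 fold change of 1.39 (SE 0.24), Xaf1, a pro-apoptotic gene, of 0.96 (SE 0.15) and Gbp3, a guanylate-binding protein, of 0.91 (SE 0.15), each with an adjusted p of 0.0038 over the list alone. Ifit3 and Gbp3 have close copies among which reads could be split. Cxcl10, an interferon-induced chemokine chosen here after its value was seen, had a log2 fold change of 0.14 (SE 0.46). The mean over the list lay between 3.49 and 4.05 log2 units in the controls and between 4.22 and 5.01 in the mimic ankles. Camera gave an adjusted p of 2.31e-15 with a preset correlation of 0.01, and an adjusted p = 0.486 with an estimated correlation. The exact permutation test of the list mean gave p = 0.0571.

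**Figure D1:**
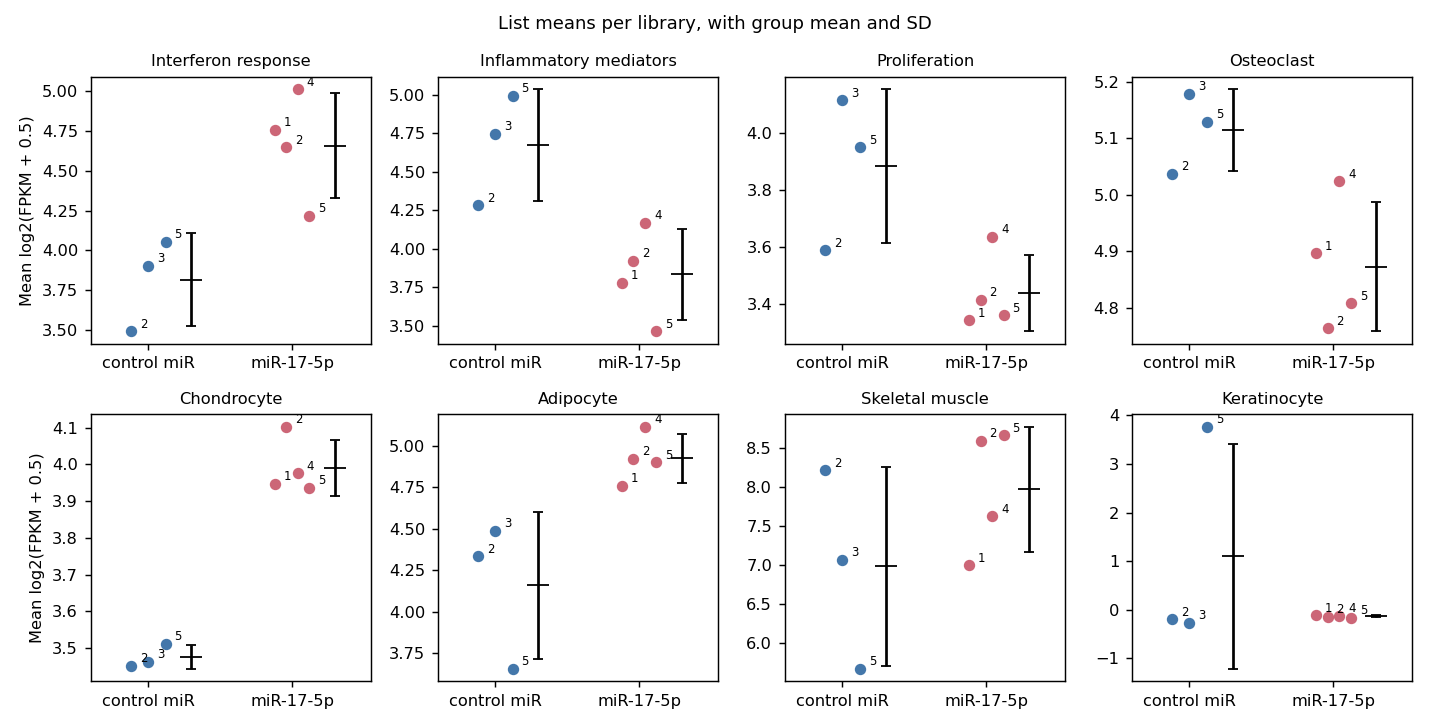
Mean log2(FPKM + 0.5) over the members of 8 gene lists (vertical axis, log2 units, a separate range per panel) in each library, by group; points are libraries with their replicate number and bars are the group mean and SD (n = 3 control, n = 4 miR-17-5p). The interferon list lay between 3.49 and 4.05 in the controls and between 4.22 and 5.01 in the miR-17-5p ankles, and the keratinocyte list was high in control replicate 5 alone.

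Inflammatory mediators were lower: 24 of 25 members tested had a lower mean in the mimic ankles, with a median log2 fold change of -0.69, and 13 were lower with p adjusted over the list alone. Cxcl5, a neutrophil-attracting chemokine, stood at 228 ± 92.0 FPKM in control and 79.8 ± 10.8 FPKM in mimic ankles. Csf3, the granulocyte growth factor, had a log2 fold change of -1.57 (SE 0.31), Ccl20 of -2.01 (SE 0.42), Il1b of -1.25 (SE 0.27) and Il6 of -1.99 (SE 0.70), all below 0.05 over the list alone. Il6 also belongs to the JAK/STAT and IL-6 list, over which it did not pass (limma adjusted p = 0.059). Over all genes tested 0 passed, and without control replicate 2 Cxcl5 did (-1.72, limma adjusted p = 0.0302), with Ccl2, Ccl7 and Ptges the other 3 members that did. Tnf had a log2 fold change of -0.16 (SE 0.39), which turned to 0.30 with the muscle list mean as a covariate, to 0.21 with the erythroid list mean and to 0.16 without control replicate 5. Camera gave the list an adjusted p of 6.14e-09, with adjusted p = 0.486 with an estimated correlation. The skeletal muscle list had a higher group mean in the mimic ankles, but the groups overlapped (exact permutation p = 0.257). Its camera call was lost with an estimated correlation (adjusted p = 0.576). With the muscle list mean as a covariate the inflammatory median was -0.31. The neutrophil list, which also holds genes of their marrow precursors, had a median of -0.54, but its groups overlapped as well (exact permutation p = 0.429). Its camera call was also lost with an estimated correlation (adjusted p = 0.576). With the neutrophil list mean as a covariate the inflammatory median was -0.48.

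Genes of JAK/STAT signalling and the IL-6 family moved in both directions, with a median log2 fold change of -0.17 over 27 members. Stat3, the main transducer of IL-6 signals (chromosome 11, 100886810 to 100939511), stood at 70.4 ± 5.25 FPKM in control and 57.8 ± 4.17 FPKM in mimic ankles, a log2 fold change of -0.28 (SE 0.080, limma adjusted p = 0.184 over all genes and 0.029 over the list alone). Stat3 also belongs to the list of reported miR-17 targets, over which it did not pass (limma adjusted p = 0.053). Lif, an IL-6 family cytokine, and Pim1, a kinase, had log2 fold changes of -1.31 and -0.79, whereas Stat2, a transducer of interferon signals, had 0.63 (SE 0.13). Jak1 hardly differed, at 50.9 ± 3.21 and 48.3 ± 2.40 FPKM with overlapping groups, a log2 fold change of -0.073 (SE 0.067). With p adjusted over the list alone, 6 members were lower and 2 higher, and over all genes tested 0 were, although 5 passed without control replicate 2, Pim1 (-0.96, limma adjusted p = 0.0427), Socs3, Osm, Il11ra1 and Jak2. Camera gave an adjusted p of 0.0056, with adjusted p = 0.486 with an estimated correlation, 0.0514 over genes with a mean of at least 5 FPKM (median -0.16) and 0.0768 with an index of clock genes as a covariate (median -0.075).

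**Figure D2:**
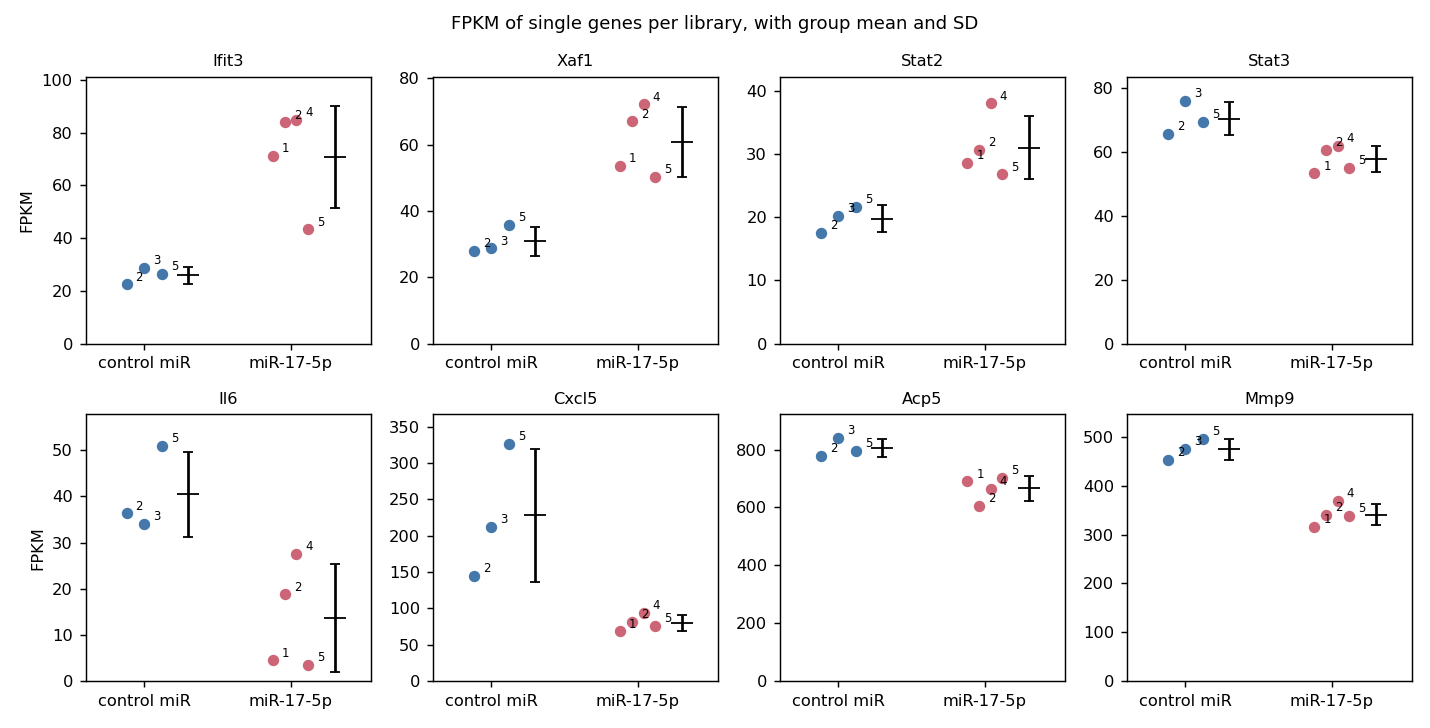
FPKM of 8 genes (vertical axis, linear from 0, a separate range per panel) in each library, by group; points are libraries with their replicate number and bars are the group mean and SD (n = 3 control, n = 4 miR-17-5p). Ifit3, Xaf1 and Stat2 stood higher in every miR-17-5p library than in any control library, and Stat3, Il6, Cxcl5, Acp5 and Mmp9 lower.

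Osteoclast genes were lower by a small amount: 15 of 16 members tested had a lower mean in the mimic ankles, with a median log2 fold change of -0.26, and 10 were lower with p adjusted over the list alone and 0 over all genes tested. Oscar, a receptor of osteoclasts, stood at 16.9 ± 1.60 FPKM in control and 12.7 ± 0.58 FPKM in mimic ankles, Ocstamp, needed for osteoclast fusion, had a log2 fold change of -0.41 (SE 0.085), and Src, a kinase of the osteoclast's resorbing border, stood at 23.3 ± 1.21 and 19.4 ± 0.68 FPKM. Ctsk, the collagen-cleaving protease of osteoclasts, stood at 1324 ± 36.8 and 1132 ± 51.4 FPKM, which did not pass over the list alone (adjusted p = 0.064, limma). Without control replicate 2 Oscar was the 1 member that passed over all genes (-0.47, limma adjusted p = 0.0367). Camera gave the list an adjusted p of 3.01e-07, with adjusted p = 0.486 with an estimated correlation. Regulators of osteoclast formation did not pass, with a median of -0.11 over 12 members (camera adjusted p = 0.122), although the adjusted p was 0.0252 over genes with a mean of at least 5 FPKM (-0.23) and 0.0487 without control replicate 5 (-0.12). Its median was -0.19 without mimic replicate 1 and -0.22 with the replicate block. Among them Tnfsf11, which encodes RANKL, stood at 15.6 ± 2.40 and 9.81 ± 4.32 FPKM, and Sfrp1, a Wnt inhibitor, at 87.0 ± 31.9 and 46.1 ± 9.62 FPKM.

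The list of matrix-degrading enzymes and their inhibitors was lower, with a median log2 fold change of -0.23 over 19 members, 8 of them lower with p adjusted over the list alone and 0 over all genes tested. The inhibitors moved apart: Timp1, among these 8, had -0.70 (SE 0.17) and Timp3 had 0.45 (SE 0.20). Timp3, Mmp2 and Mmp12 were the 3 members with a higher mean. Mmp9, a gelatinase, stood at 475 ± 21.6 FPKM in control and 341 ± 21.9 FPKM in mimic ankles, and Mmp3, a stromelysin, at 1332 ± 297 and 751 ± 170 FPKM. Plau, the urokinase plasminogen activator, and Adamts4, an aggrecanase, had log2 fold changes of -0.54 (SE 0.10) and -0.85 (SE 0.19), while Mmp13, a collagenase, had -0.23 (SE 0.17), or -0.066 without control replicate 3 and -0.12 without mimic replicate 2. Camera gave an adjusted p of 0.0012, with adjusted p = 0.486 with an estimated correlation. With genes of a mean of at least 5 FPKM the median was -0.35, with the replicate block -0.48 and with the neutrophil covariate -0.14, and without control replicate 2 3 members passed over all genes, Adamts5, Plau (-0.65, limma adjusted p = 0.0302) and Adamts4 (-1.09, limma adjusted p = 0.0268).

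All 18 cell division genes had a lower mean in the mimic ankles, with a median log2 fold change of -0.45, and 14 were lower with p adjusted over the list alone and 0 over all genes tested. Cdk1, the mitotic kinase, stood at 22.9 ± 3.02 FPKM in control and 15.2 ± 1.69 FPKM in mimic ankles, and Ccnb1 and Aurka had log2 fold changes of -0.58 (SE 0.14) and -0.52 (SE 0.13). Camera gave an adjusted p of 2.09e-09, with adjusted p = 0.486 with an estimated correlation. The list means overlapped between the groups, and their exact permutation test gave p = 0.0857. The list of immediate early and heat shock genes, chosen as a sign of handling, was also lower, with a median of -0.37 (camera adjusted p = 0.0038, and adjusted p = 0.509 with an estimated correlation). Its heat shock members hardly differed: Hspa1b, Dnajb1 and Hspb1 had log2 fold changes of -0.018, -0.066 and 0.070. Junb, Ier2 and Btg2, induced within minutes by stress or growth factors, had log2 fold changes of -0.83, -0.65 and -0.35, and 2 of 15 members were lower with p adjusted over the list alone and 0 over all genes tested. Without control replicate 2, 6 cell division genes, among them Cdk1 (-0.69) and Aurka (-0.67), and Junb (-0.98) passed over all genes, these 3 at limma adjusted p of 0.0396, 0.0335 and 0.0470. The immediate early median was -0.23 without control replicate 3, -0.64 without control replicate 5, -0.58 with the muscle covariate and -0.75 with the erythroid covariate.

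The list of neutrophils and their marrow precursors had a lower mean in all 18 members, with a median log2 fold change of -0.54. The members differed widely. Cxcr2, the chemokine receptor of neutrophils, had a log2 fold change of -1.43 (SE 0.26), whereas Camp, Ngp and Ltf had -0.013, -0.15 and -0.17 (SE 0.61, 0.62 and 0.62). Csf3r, the receptor of Csf3, stood at 77.9 ± 16.2 and 36.6 ± 9.63 FPKM. S100a9, a calcium-binding protein of neutrophils, stood at 2624 ± 833 and 1326 ± 448 FPKM, with overlapping groups. Of the members, 2 were lower with p adjusted over the list alone and 0 over all genes tested, where Cxcr2 passed without control replicate 2 (-1.76, limma adjusted p = 0.022). Camera gave an adjusted p of 0.0013, with adjusted p = 0.576 with an estimated correlation, and 0.259 without control replicate 3, where the median was -0.14. The median was -0.83 without control replicate 2 and -0.16 without mimic replicate 5. The call was also lost with the immediate early list (-0.23, adjusted p 0.136) or the macrophage list (-0.085, 0.0584) as a covariate, and the median was -0.18 with the muscle and -1.24 with the erythroid covariate.

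Genes of adipocytes and cartilage were higher in every mimic library than in any control library when averaged over their lists. The adipocyte list had a median log2 fold change of 0.77, with 12 of 14 members higher with p adjusted over the list alone, and the cartilage list 0.54, with 4 of 18, and 0 of either over all genes tested, where Fabp4, an adipocyte fatty acid carrier, passed without control replicate 2. Pparg, the master regulator of fat cells, stood at 6.14 ± 0.45 FPKM in control and 8.68 ± 0.82 FPKM in mimic ankles, and Lep and Lipe had log2 fold changes of 1.09 (SE 0.23) and 0.44 (SE 0.11). Col2a1, the main collagen of cartilage, stood at 32.9 ± 6.46 and 53.1 ± 9.20 FPKM, and Clec3a and Snorc, both cartilage genes, had log2 fold changes of 1.13 (SE 0.22) and 0.92 (SE 0.24). Camera gave an adjusted p of 6.14e-09 for adipocytes and 3.24e-05 for cartilage, with adjusted p = 0.486 and adjusted p = 0.126 with an estimated correlation. An exact 2-sided permutation test of each list mean gave p = 0.0286 for both, the smallest the 35 splits can give, and an adjusted p of 0.229 over 16 cell type lists. The adipocyte median was 0.51 without control replicate 5 and 0.44 with the erythroid covariate, and the cartilage median was 0.26 without control replicate 3, 0.24 with the replicate block and 0.34 with the index of clock genes.

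Markers of other tissues varied between libraries of a group. The skeletal muscle list had a median log2 fold change of 1.04 with a list mean of 6.99 ± 1.27 log2 units (SD, n = 3) in control and 7.97 ± 0.80 (SD, n = 4) in mimic ankles (exact permutation p = 0.257). Camera gave it an adjusted p of 0.00016, with adjusted p = 0.576 with an estimated correlation. Without control replicate 5 its median was 0.36 and its camera adjusted p was 0.057, and its median was 1.64 without control replicate 2, 1.69 with the replicate block, and 0.57, 1.68 and 0.52 with the neutrophil, immediate early and macrophage covariates. Tnni1, Myl1 and Mylpf, all of the contractile apparatus, had log2 fold changes of 1.20, 1.29 and 1.17. Without control replicate 5 these were 0.765, 0.64 and 0.62, and without control replicate 2 Myl1 was 1.95 and Mylpf 1.80. Of the 20 members 0 passed with p adjusted over the list alone or over all genes tested. The erythroid list had a median of 1.06 (camera adjusted p = 0.00047, and adjusted p = 0.509 with an estimated correlation), or 0.70 without control replicate 5, and 1.75 and 1.60 with the neutrophil and immediate early covariates. Its members Rhag, Trim10 and Tspo2 had log2 fold changes of 1.01, 1.18 and 1.06. Rhag was 0.63 without mimic replicate 4 and Tspo2 0.70 without control replicate 5. Of the 12 tested 0 passed with p adjusted over the list alone or over all genes tested. With the index of clock genes as a covariate the calls of both lists were lost, at medians of 0.18 for muscle and 0.26 for erythroid genes (adjusted p 0.507 for each).

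Among bone-forming, nerve and vessel genes the differences were smaller. Osteoblast and osteocyte genes had a median of 0.26, with all 18 members at a higher mean (camera adjusted p = 0.00011, and adjusted p = 0.486 with an estimated correlation), or 0.39 without control replicate 2, 0.155 without control replicate 5 and 0.17 with the muscle covariate. Omd, a proteoglycan of bone, stood at 17.2 ± 2.70 FPKM in control and 27.2 ± 1.59 FPKM in mimic ankles, the 1 of 18 members higher with p adjusted over the list alone. Over all genes tested 0 passed, and without control replicate 2 Omd did (0.77, limma adjusted p = 0.025). Bglap and Bglap2, the osteocalcin genes, whose reads are uncertain because the copies are nearly identical, had log2 fold changes of 1.49 and 1.32, or 0.76 and 0.67 without control replicate 5. Peripheral nerve genes, Cnp, Gldn and Ncmap among them with 0.30, 0.30 and 0.50, had a median of 0.29 (camera adjusted p = 0.0050, and adjusted p = 0.576 with an estimated correlation). Without control replicate 5 the nerve median was 0.054 and its adjusted p was 0.190, and the call was lost with the muscle list as a covariate (0.025, 0.570), and with the neutrophil, macrophage and clock covariates (medians 0.20, 0.145 and 0.13, adjusted p 0.0765, 0.0949 and 0.355). With the replicate block the nerve median was 0.51. Without control replicate 5 Gldn was 0.13 and Ncmap 0.17. Without control replicate 2 Ncmap was 0.79 and Cldn5 0.63, and without control replicate 3 Robo4 was 0.073. Endothelial genes, Tek, Cldn5 and Robo4 among them with 0.21, 0.41 and 0.17, had a median of 0.10 (camera adjusted p = 0.020, and adjusted p = 0.533 with an estimated correlation). With p adjusted over the list alone, 0 of 12 nerve and 0 of 15 endothelial genes passed. The endothelial call was lost without control replicate 3 (median 0.022, adjusted p = 0.276) and without mimic replicate 1 (median 0.068, adjusted p = 0.0551). It was also lost with the replicate number as a block (-0.015, 0.680), and with the neutrophil, immediate early and clock covariates (medians 0.093, 0.063 and 0.0021, adjusted p 0.0556, 0.141 and 0.603). Without control replicate 2 Pmp2, a myelin gene, passed over all genes.

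The remaining lists of cell types and organelles did not pass camera in all 7 libraries under the settings chosen for the test, and several passed under other settings. The gene said to lead a list is its member with the smallest p. It need not have the largest change or the direction of the list. Macrophage and monocyte genes had a median log2 fold change of -0.11 (adjusted p = 0.108), with the receptor Cd14 at 86.3 ± 17.2 FPKM in control and 52.6 ± 9.20 FPKM in mimic ankles. T and NK cell genes had a median of -0.14 (0.209), led by Cd3d at -0.53, and B lineage genes of 0.30 (0.0994), led by Ebf1 at 0.16. Synovial fibroblast genes had a median of 0.15 (0.197), led by Htra4 at 1.29, and tendon genes of 0.12 (0.0741), led by Kera at 0.96 (SE 0.21), with 4 of 12 members higher with p adjusted over the list alone. Megakaryocyte genes had a median of 0.073 (0.756), led by Pf4 at -0.19, nuclear genes of oxidative phosphorylation of 0.043 (0.199), led by Cox7a1 at 0.86, and 7 mitochondrial genes of 0.067 (0.704), led by mt-Nd6 at -0.23. Keratinocyte genes had a median of -1.43 (0.0804): Krt14, a keratin of the epidermis, stood at 13.8 FPKM in control replicate 5 and at 0.020 FPKM or less in the other libraries, and without control replicate 5 its log2 fold change was 0.014.

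For several of these lists the outcome hung on single libraries or settings. Among the genes named, Cd3d was -0.29 without mimic replicate 5, and Cox7a1 was 0.46 without control replicate 5 and 0.48 without mimic replicate 5. The gene mt-Nd6 was -0.13 without control replicate 5 or mimic replicate 4. Pf4 ranged from -0.34 without mimic replicate 4 to -0.034 without mimic replicate 5. B lineage genes passed without control replicate 3 (median 0.48, adjusted p 0.0081) and without mimic replicate 2 (0.56, 0.0014), and had a median of 0.074 without mimic replicate 5. Macrophage genes passed without mimic replicate 1 (-0.14, 0.0449) or 4 (-0.18, 0.0215), and had a median of -0.058 and -0.052 without mimic replicates 2 and 5. T and NK genes passed without mimic replicate 1 (-0.31, 0.0030), with a median of -0.030 without mimic replicate 2. Tendon genes passed without control replicate 3 (0.13, 0.0081) and without mimic replicate 4 (0.18, 0.0393), with a median of 0.042 without mimic replicate 2. Synovial fibroblast genes passed without control replicate 3 (0.13, 0.0236), and megakaryocyte genes without mimic replicate 5 (0.42, 0.0492). Oxidative phosphorylation genes passed without control replicate 2 (0.10, 0.0439) and mimic replicates 1 (0.11, 0.0050) and 4 (0.085, 0.0393). Keratinocyte genes passed without control replicate 2 or 3 (-2.18 in each, 0.0296 and 0.0063). With the replicate number as a block the group difference rests on replicates 2 and 5 of each group alone. In that fit the B lineage (0.62, 0.0063), macrophage (-0.28, 0.0087), T and NK (-0.42, 0.00037), tendon (0.21, 0.0234), oxidative phosphorylation (0.17, 0.00018) and keratinocyte (-2.18, 0.0214) lists passed. With the erythroid covariate the B lineage (0.63, 0.00093), macrophage (-0.25, 0.0064), oxidative phosphorylation (0.13, 0.0025) and megakaryocyte (-0.81, 6.33e-07) lists passed. Tendon genes also passed over genes with a mean of at least 5 FPKM (0.0293) and with quantile normalization (0.0429), keratinocyte genes with no filter (-0.90, 0.0010) and with library weights (-1.83, 0.0348), and oxidative phosphorylation genes as lower with the muscle covariate (-0.082, 0.0209).

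The seed match of the mimic did not stand out among other sequences. Genes whose 3 prime UTR holds a match to the miR-17-5p seed (2701 genes with GCACTTTA, GCACTTT or CACTTTA) had a mean log2 fold change of 0.0019, and those without a match (7496 genes) of 0.015, a difference of -0.013. The exact 2-sided permutation test over 35 splits gave p = 0.629, and GCACTTT ranked 173 from the lowest of 420 heptamers of the same bases. The difference was 0.0055 without control replicate 3 and -0.033 without control replicate 2. In 572 genes with at least 2 matches, a test chosen after the data were seen, it was -0.038, which ranked 86 of 420 heptamers (exact permutation p = 0.371). Genes widely reported as miR-17 targets had a median log2 fold change of -0.073 over 34 members (camera adjusted p = 0.197), with 1 higher (Zbtb4, a transcriptional repressor, 0.26) and 1 lower (Smad7) with p adjusted over the list alone and 0 over all genes tested, where Hif1a, a hypoxia regulator, passed without control replicate 2. The median was -0.014 without control replicate 3, -0.038 without mimic replicate 2 and -0.026 with the replicate block. Smad7, an inhibitor of TGF-beta signalling, stood at 6.35 ± 0.23 FPKM in control and 4.82 ± 0.24 FPKM in mimic ankles, while Cdkn1a, a cell cycle inhibitor, and Tgfbr2, a TGF-beta receptor, had log2 fold changes of -0.23 and 0.067. Tgfbr2 was 0.013 without mimic replicate 1 and 0.12 without control replicate 3. Mir17hg, the host transcript of the endogenous miR-17 cluster, from which an injected mimic does not come, had a log2 fold change of -0.11 (SE 0.24). It was -0.40 without control replicate 2 and 0.077 without control replicate 3. The mature microRNA was not measured.

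**Figure D3:**
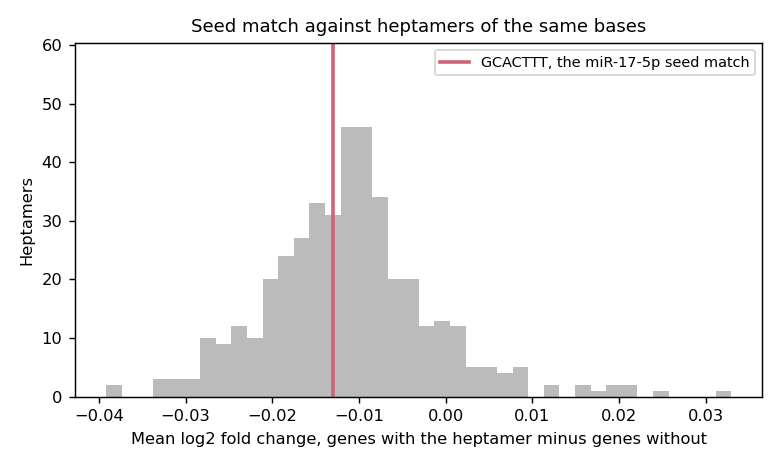
Number of heptamers (vertical axis) by the difference in mean log2 fold change between genes whose 3 prime UTR holds the heptamer, or its last 6 bases followed by A, and genes whose UTR lacks even those 6 bases (horizontal axis, log2 units), for the 420 heptamers made of the same bases as the miR-17-5p seed match; the line marks that match. The match lies at -0.013, where the median heptamer lies at -0.011.

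Some genes of the circadian clock were picked out after their values were seen. Dbp, a clock output gene, stood at 24.7 ± 14.4 FPKM in control and 55.5 ± 8.89 FPKM in mimic ankles, and Arntl, a clock activator of opposite phase, at 4.56 ± 1.36 and 2.74 ± 1.01 FPKM. Neither passed over all genes with limma (adjusted p = 0.176 and 0.293).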

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

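Among 80 named genes and 26 list means, the 4 mimic libraries were examined for a library far from the others, and 6 genes had one, where chance flags about 1 in 20 and so about 5.3; groups of 3 were not tested. The gap to the nearest library, as a share of the whole range, was 0.879 for Ctsk and 0.836 for Src, both low in mimic replicate 2. It was 0.861 for Plau and 0.936 for Ccnb1, both high in mimic replicate 4, and 0.910 for Smad7, low in mimic replicate 5. For Krt14 it was 1.00, from 0.020 FPKM in mimic replicate 1 against 0 in the other mimic libraries, a value at the floor.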

How the results depend on the processing

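The tests with limma-voom, with 2 or more seed matches and with neutrophil, immediate early, macrophage and clock covariates were chosen after the result was seen. The count of 0 genes past an adjusted p of 0.05 held in each direction under the other settings in which genes were counted (the neutrophil, immediate early and macrophage covariates were run for lists alone), except that 1 lower gene passed with no filter and 115 higher and 203 lower passed without control replicate 2 (range 0 to 115 and 0 to 203 when leaving out each library). The count with an unadjusted p under 0.05 was 2356, 1406 with the erythroid covariate, 411 with the clock index and 1216 to 3833 when leaving out each library. Replicate numbers 2 and 5 occur in both groups, but the labels do not say that they pair. The file headers number all libraries in a single series with gaps, controls first, so a shared replicate number need not mark a pair. Deviations of same-numbered libraries correlated at 0.535 and -0.435. The replicate block takes the group difference from replicates 2 and 5 of each group alone, since each other number has a single library. With it 1064 genes had an unadjusted p under 0.05, 0 passed, and the seed difference was 0.0051. With the block the endothelial median, called by camera without it, was -0.015. Camera called 8 lists higher and 7 lower, and 0 and 0 with an estimated correlation (lowest adjusted p 0.126). Fry's test of a shared direction called 0 and 0 (lowest adjusted p 0.052), and its mixed test passed 14 lists. Leaving out each library gave 6 to 10 higher and 7 to 9 lower lists, and seed differences of -0.033 to 0.0055. The direction given by camera, which sets a list against all other genes and can differ from the sign of its median, turned in some settings for lists not called, with these medians. The megakaryocyte median was -0.11 with the block, -0.81 with the erythroid covariate, -0.35 with the clock index and -0.20 to 0.42 leaving out each library. The mitochondrial median was 0.034 with no filter, -0.059, -0.028 and -0.0088 with the muscle, neutrophil and macrophage covariates, and -0.020 to 0.12 leaving out each library. The oxidative phosphorylation median was -0.082, -0.065 and -0.057 with the same covariates and -0.013 to 0.11 leaving out each library. The T and NK median was 0.066 with the muscle covariate and -0.043 with the clock index, the B lineage median -0.033 with the immediate early covariate, and the keratinocyte median -0.15 with the clock index and -2.18 to 0.076 leaving out each library. The reported targets' median was 0.019 with the clock index. Tnf was 0.30, 0.21 and 0.97 with the muscle, erythroid and clock covariates, and Mir17hg 0.15 with muscle and 0.45 with the clock index. With the clock index Jak1 was 0.044 and Robo4 -0.034. Leaving out each library gave -0.60 to 0.16 for Tnf, -0.40 to 0.077 for Mir17hg and -2.41 to 0.014 for Krt14, and 19 of the 80 named genes passed without control replicate 2. List calls lost in single settings, and those gained in settings chosen before the data were examined, are given with each list. The cause was not tested for these. With a mean of at least 5 FPKM the keratinocyte, megakaryocyte and T and NK lists and Tgtp2, Tnfsf10, Tnf, Mir17hg, Lep, Snorc, Rhag, Trim10, Tspo2, Csf3, Krt14, Gldn, Ncmap and Cd3d were not tested.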

Other observations

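The gene families and the clock genes in this part, and the tests of neutrophil, macrophage and lymphocyte shares, of handling, of a wrong label, of the muscle content of control replicate 2 and of its clock index, were chosen only after the result was seen. So was the rule that an explanation stays open where the share of a value kept with a covariate lies on both sides of 0.5 when each library is left out. After Iigp1 and Tgtp2 were seen among the genes with the smallest p, their families were looked up, so these counts describe the families and do not test them. All 8 guanylate-binding proteins tested had a higher mean, with a median log2 fold change of 0.91, and 6 did not overlap between the groups. Of all genes tested 15.3% did not overlap, where chance gives 5.71%. All 6 immunity-related GTPases, Irgm1, Irgm2, Igtp, Iigp1, Tgtp1 and Tgtp2, had a higher mean without overlap, with a median of 1.01. Reads can be split among close copies in both families.

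None of the 14 clock genes picked out passed over all genes with limma. All 11 output and repressor genes had a higher mean in the mimic ankles, from Nr1d1 with a log2 fold change of 0.049 to Dbp with 1.29, and all 3 activators, Arntl, Clock and Npas2, a lower one, at -0.66, -0.26 and -0.80. The index, outputs minus activators, was 0.77 ± 0.80 log2 units (SD, n = 3) in the controls and 2.05 ± 0.44 (SD, n = 4) in the mimic ankles, values that describe genes picked out for their values and do not test them. It was 1.69 in control replicate 2 and 0.28 and 0.34 in the other controls, against 1.57 to 2.63 in the mimic ankles. A candidate explanation is that ankles were dissected at different times of day. With the index as a covariate 411 genes had an unadjusted p under 0.05, but an index that nearly parts the groups lowers this count whatever the cause, so the count does not speak for it. The labels give no times, and an effect of the mimic or of inflammation on the clock remains open.

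Leaving out control replicate 2 raised the number of genes past an adjusted p of 0.05 from 0 to 318, 0 of them in the interferon list, although Tgtp2, an interferon-inducible GTPase gene, was among them. On those genes control replicate 2 lay 0.701 of the way from the other controls to the mimic mean, which largely restates that they pass only without it. On the 300 genes with the smallest p without each library in turn it lay at 0.685, the other controls at 0.306 and -0.0907 and the mimic ankles at 0.701 to 0.855. A wrong label cannot be told apart from an ordinary difference between ankles: it lay between the groups, and its interferon list mean of 3.49 was the lowest of all 7 libraries. Its clock index lay 0.792 of the way, so a shared time of dissection may account for its place, and its muscle content stays open too, since with the muscle list as a covariate 0 genes passed but all 7 libraries without it also gave 0.

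For the higher interferon-stimulated genes, differing shares of muscle, of blood-forming marrow and of T cells, NK cells or macrophages are argued against; shares of fat and cartilage were not tested. With the muscle and erythroid list means as covariates the list median was 1.05 and 0.63 against 0.88 without them, and more T cells, NK cells or macrophages would raise lists whose higher median was -0.11. With the clock index the median was 0.88 (0.875), but the share kept ranged from -0.558 to 1.36 when each library was left out, so time of day cannot be told apart from the group. A response to the mimic, the difference between groups that the design names, stays open and was not tested.

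For the lower inflammatory mediators, handling before freezing is argued against, since with the immediate early list as a covariate the median was -0.74 against -0.69 without it. A larger share of muscle may account for part: with that covariate the median was -0.31. The share kept was 0.446, under the 0.5 set beforehand as the mark of this explanation. It ranged from 0.412 to 0.662 when each library was left out, so by the rule chosen later muscle cannot be told apart from the group. A smaller share of neutrophils or their marrow precursors (-0.48, share kept 0.366 to 0.865) and time of day (-0.47, 0.363 to 2.13) cannot be told apart from the group either. An effect of miR-17-5p on these genes is the biological explanation the design names, and it was not separated from them.

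The osteoclast median of -0.26 was -0.24 with the muscle covariate and -0.23 with the macrophage covariate. Seed-site repression by the mimic would put GCACTTT among the lowest heptamers. Its rank was 173 of 420, 86 for genes with at least 2 matches and 287 with 8mer matches alone. These ranks argue against a broad effect of that kind in whole ankles.

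Chance could not be excluded for the counts. Of the 35 splits of the 7 libraries, the real one counted among them, 3 gave as many genes with an unadjusted p under 0.05 as the real 2356 (highest other 2980), and 8 gave as many lists past camera as the real 15 (highest other 17). Every mixed split passed at least 5 lists, so a camera call with the preset does not by itself tie a list to the groups. For genes past an adjusted p of 0.05 the real count was 0, which all 35 splits reach by necessity, so that comparison says nothing. The highest other was 155. That split set control replicate 2 and mimic replicates 2 and 5 against the rest, and these are the libraries with the highest muscle list means (8.22, 8.60 and 8.67), which points to a structure of the samples other than the groups.

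With no filter on low values, Scarna2, a small Cajal body RNA of chromosome 3, was the single gene past an adjusted p of 0.05 (0.000309). It had 1 read in each control library and 0 in each mimic library.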
